A study of Homo sapiens with 12 samples.

How the data were processed

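Nascent RNA was measured by TT-TL-seq in HEK-293T cells, a human embryonic kidney line that is easy to transfect. Per the labels, RNA made during a 5 min pulse of 1 mM 4-thiouridine (s4U) at the end of each treatment was enriched and then treated with TimeLapse chemistry. Libraries came from a stranded total RNA kit, and RNA of Drosophila S2 cells had been added at 4% of each sample, per the series design text. The series lists 12 samples, of which 8 enriched libraries in 5 conditions were analysed. Cells with a control siRNA (siC), cells with the control siRNA and 80 mM KCl for 1 h (KCl) and cells with an siRNA against Int11 for 48 h (siInt11) gave 2 libraries each. Knockdown cells that stably expressed siRNA-resistant Int11, wild type or with the E203Q mutation, gave 1 library each. The other 4 samples, control libraries of siC and KCl cells without an s4U pulse in their labels, were not analysed here. No label says whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

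The values are a scaled signal per gene or per region in 3 tables deposited by the authors: genes of the KCl series, genes of the siInt11 series, and regions downstream of genes (DoGs) in all 8 libraries. In each library outside the KCl group the low values fell on the rounded multiples of a fixed step, for 98.5 to 100% of low values, so the authors had multiplied reads by 1 factor per library and rounded the product. The factor itself, the aligner, the counting tool and its strand setting, the genome build, and the way DoG regions were picked are not given in the sources used here. The submitters' processing notes name edgeR and bedtools without a role. Gene symbols were used as the deposited tables give them, without coordinates. In the region table the siC columns carry another name and were assigned by elimination, and its replicates carry the letters G and I, which the labels do not tie to replicates 1 and 2. The gene tables held 24240 rows and 0 rows named for Drosophila genes, and the region table held 7214 rows. Among gene symbols, 98 stood on several rows, and 25 had been turned into dates. The siC columns of both gene tables differed on 551 of 23996 rows, by more than 1 on 88.

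Depth was estimated from the step of the low values. Total values were 69.24 and 83.64 M for siC, 31.48 and 36.23 M for KCl, 58.11 and 82.64 M for siInt11, 57.51 M for the wild-type rescue and 64.8 M for the E203Q rescue. The estimated reads behind them were 26.1 and 43.0 M for siC, 44.3 and 57.1 M for KCl, 27.9 and 65.2 M for siInt11, 21.7 M for wild type and 35.5 M for E203Q. The KCl libraries were therefore the most deeply read per unit of value, at 0.711 and 0.634 units per read, and a value of 3 in siC library 1 stands for about 1 read. In the KCl libraries the steps are below 1, so their depth is an estimate with less certainty, and KCl library G of the region table had a step of 0.627 that neither KCl column of the gene table shared. Means are given ± SD over 2 libraries unless stated otherwise.

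Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a variance trend and the robust option, over the libraries of the groups compared, keeping the deposited scaling. Genes and regions with a value of at least 20 in at least 2 of the compared libraries were tested, and a Benjamini-Hochberg adjusted p under 0.05 was taken as the threshold. A fold change on the log2(value + 1) scale understates the change of low genes. limma's prior degrees of freedom had an infinite median in every level comparison, so for most genes the spread was pooled over genes of like level. The robust option gives genes of outlying spread a finite prior, so these were judged partly by their own replicates. The change of a DoG region relative to its host gene was tested as the interaction of measure (gene or region) and group. Host calls were compared by Fisher's exact test, two-sided. The overlap of both sets of raised regions was set beside the product of independent lists and beside 100 simulations of unchanged groups against the shared siC libraries. The rescues, with 1 library per condition, were described by medians. Percentiles among random lists matched on mean value, which were planned, are not given, because the sets were chosen against the siC libraries that the ratios use.

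The plan, fixed before the data were examined, was a quasi-likelihood count test with a second count tool as its alternative, and limma on log2(value + 1) if the values proved to be normalized. They did, so the count tests, voom and spike-in scaling were not run. The plan also named TMM on human genes as the scaling where no spike-in rows were present. The deposited scaling was kept instead because TMM centres the genes and would remove a general change, and the TMM counts are printed beside the counts of each comparison where the split moved. The filter, the robust option and the retained scaling were settled after the unit had been seen, the robust option after a fit without it had been looked at. The ratio model was planned with each library as its own block. Because no label ties region columns to numbered gene columns, the reported ratios were fitted without the block. The steps of low values tie letter G to replicate 1 and I to 2 for all libraries but KCl library G, which was tied by elimination. Under this tie the log2 differences between replicates correlated between genes and regions at 0.11 in siC for the KCl table and 0.16 for the siInt11 table. In KCl they correlated at 0.20 and in siInt11 at 0.16. These correlations cannot see a shift common to a whole library. Between the siInt11 libraries its median was 0.46 for genes and 0.57 for regions. The fit without the block counts such a shift as spread. The blocked model was then run with this tie as an alternative added after seeing the data, and its counts are printed beside those of the ratios.

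The 17 gene lists were fixed before the data were examined: osmoadaptation genes linked to NFAT5, immediate early genes, heat shock proteins, the unfolded protein and integrated stress response, p53 targets, Integrator subunits, cleavage, polyadenylation and termination factors, RNA polymerase II and elongation factors, replication-dependent histones, cytosolic ribosomal proteins, mitochondrially encoded genes, spliceosomal snRNA genes, cholesterol synthesis, S and G2/M cell cycle genes, glycolysis and HIF1 targets, host genes known for DoGs under osmotic stress, and markers of other cell types. Lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation. Named genes followed a rule fixed at the same time: the 8 risen and 8 fallen genes of largest fold change past the threshold with a mean of at least 50 in the higher group and separated libraries, up to 4 members of each list with the smallest p, Int11 (listed as CPSF3L), OSGIN2, CXXC4 and RSRP1, and for regions the 8 raised and 4 lowered of largest change with a mean of at least 20, or 4 and 4 for ratios. Items outside the rule are said to be chosen after their values were seen. The values of 3 genes that the rule named are not reported here.

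Alternatives were human TMM, median-ratio and total-value scaling, other low-value filters, a 2-fold minimum, the replicate number as a block, all libraries of a table in 1 fit, and each library left out in turn. A pseudocount of 10, limma without the robust option, 2 prior degrees of freedom, ratio tables put on 1 scale and ratios with each library as its own block were added after seeing the data. Gene spans, strands and neighbours for tests of explanations came from the GENCODE annotation of GRCh38 by symbol, which placed 91.1% of the genes tested for KCl, and no coordinate is printed because the authors' build is not known. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Simulated data held 200 changed genes or regions and a fixed dispersion of 0.02. On these data the fits recovered, for KCl, 54% of genes changed 2-fold and 100% of genes changed 4-fold. For siInt11 they recovered 6% and 98%. For DoG regions they recovered 68% and 100% for KCl, 1% and 96% for siInt11, and 9% and 100% for KCl against siInt11. For DoG to host ratios they recovered 13% and 99.0% for KCl, and 0% and 55.2% for siInt11. In the KCl comparisons far more genes, regions and ratios were called than were changed in the simulation. The KCl shares therefore do not measure the sensitivity of the reported KCl fits. Genes that share sequence with near-identical copies (snRNA, histone and HSPA1A/HSPA1B genes) are uncertain where counting could split their reads, and so are overlapping and antisense genes.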

Results

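The series asked which changes of transcription accompany the induction of DoGs, RNAs that run past the end of their gene, after hyperosmotic stress, and what loss of Int11 does to the same regions. Int11 is the endonuclease subunit of Integrator, the complex that cleaves nascent snRNA and terminates polymerases at many promoters. Nascent RNA of HEK-293T cells was read in 2 siC, 2 KCl and 2 siInt11 libraries and in 1 library each of knockdown cells with wild-type or E203Q Int11. All values are the authors' scaled signal, and every adjusted p comes from limma. Total gene values ranged from 31.48 M in KCl library 1 to 83.64 M in siC library 2, and totals over DoG regions from 6.65 M in siC library G to 10.39 M in siInt11 library I. Replicates of a group differed, as a median over genes, by 0.24 on the log2 scale for siC, 0.21 for KCl and 0.46 for siInt11.

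The targeted gene was checked first. CPSF3L, the symbol under which Int11 is listed, had values of 3998 and 5987 in siC, 1719 and 2545 in siInt11, 12383 in the wild-type rescue and 17336 in the E203Q rescue. It fell by 1.23 on the log2 scale with siInt11 (SE 0.32, adjusted p = 0.013). An siRNA acts on mature RNA, so nascent signal need not fall with it and does not measure the knockdown itself. Both rescue libraries lay above both siC libraries, and the rescue cells carry Int11 transgenes, per the labels. The fall lost its call without siC library 1 (log2 change -1.52) and without siC library 2 (-0.93), although both siInt11 values lay below both siC values. In KCl, with the control siRNA, the gene had lower values still, of 1353 and 1560.

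Under KCl most genes were lower on the deposited scale, a drop that TMM takes out and a smaller set rose. SLC6A12, the betaine transporter of the osmotic response, rose from 30.5 ± 2.12 in siC to 693.5 ± 344 in KCl (n = 2 each, log2 change 4.37, SE 0.41, adjusted p = 9.4e-26). GADD45B, an early stress gene, rose from 496.5 ± 139 to 6587 ± 3584 (log2 change 3.64, SE 0.24, adjusted p = 4.0e-49). TPH2, the neuronal tryptophan hydroxylase, went from 12 ± 5.66 to 3298.5 ± 752. In the other direction FIP1L1, a subunit of the polyadenylation machinery, fell from 11909 ± 2529 to 720.5 ± 24.7 (log2 change -4.03, SE 0.22, adjusted p = 7.0e-74), and SLC7A11, the cystine transporter, from 7243 ± 498 to 606 ± 67.9. With the deposited scaling 2326 of 19120 genes rose and 13280 fell, and the median gene changed by -1.41 on the log2 scale, a fold of 0.376. The number fallen rests on that scaling, since TMM on human genes, which centres them, gave 6516 risen and 6896 fallen, median-ratio scaling 6626 and 6814, and total values 5529 and 8127. Without KCl library 2, 1408 genes rose. Rows of the ribosomal RNA repeat made up 10.97 and 13.02% of all gene values in siC, 24.44 and 23.14% in KCl and 9.3 and 12.52% in siInt11.

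The genes of largest rise were silent or nearly so in siC, and genes under 20 in both siC libraries were tested only where both KCl values reached 20. KLHL40, a muscle kelch protein, was listed at 0 in both siC libraries and at 393.5 ± 16.3 in KCl. GPR55, TLR7 and LOC101928936 were likewise listed at 0 in siC and at 352 ± 170, 300 ± 84.9 and 245.5 ± 95.5 in KCl. ADGRF4 went from 2 ± 2.83 to 1025.5 ± 569, CXorf36 from 6.5 ± 9.19 to 1472 ± 379 and CTAGE11P from 1 ± 1.41 to 555.5 ± 105. The largest falls were those of TRHDE-AS1 (705.5 ± 71.4 to 8 ± 5.66), ZFP37, a zinc finger gene (1735.5 ± 493 to 21 ± 4.24), SMIM3 (504 ± 49.5 to 7.5 ± 7.78), AIRN (794.5 ± 161 to 15 ± 8.49), the collagen gene COL10A1 (366 ± 22.6 to 6 ± 0), RAB41 (239 ± 75 to 4.5 ± 3.54), RIPPLY2 (540 ± 276 to 10.5 ± 6.36) and SLURP1 (74 ± 14.1 to 0.5 ± 0.707). The siC values of the risen genes are a few reads, so their folds have little precision. The KCl values of the fallen genes, at 0.5 to 21, are low too. They stand for somewhat more reads, at 0.711 and 0.634 units per read.

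Among the stress lists, osmoadaptation genes had a median log2 change of -1.15, which turned to 0.25 with TMM scaling. Of 15 tested members 2 rose and 12 fell, also when adjusted over the list alone (7 and 4 with TMM). AQP1, a water channel, rose with SLC6A12 (146.5 ± 46 to 362.5 ± 53, log2 change 1.33), while SLC12A2, the Na-K-Cl cotransporter that cells use to regain volume, fell by 2.14 on the log2 scale and its kinase OXSR1 fell by 2.67. Immediate early genes split, with 7 of 32 risen and 12 fallen over all genes and over the list alone (adjusted over the list alone, 7 and 12, or 19 and 3 over all genes with TMM). GADD45B, ARC (2.38), KLF2 (1.94) and ZFP36 (1.54), whose product degrades unstable mRNAs, rose, and EGR2 (-3.46), NR4A2 (-2.24) and GADD45A (-2.08) fell. Their median of -0.32 was 1.09 above that of all genes and became 1.08 with TMM, and camera placed the list above other genes (adjusted p = 0.0075, 0.149 without KCl library 2, adjusted p = 0.999 with an estimated correlation). Of 16 heat shock genes 2 rose and 10 fell, with the same counts adjusted over the list alone and a median of -0.82 that turned to 0.58 with TMM (9 and 5). HSPA1A rose from 11556 ± 2937 to 19277 ± 7375 and HSPA1B from 14530 ± 4110 to 22676 ± 8263, a near-identical pair whose reads could be split, while the co-chaperones CHORDC1 (-3.09), HSPH1 (-2.35) and BAG3 (-2.39) fell. In the unfolded protein and integrated stress response 0 of 17 genes rose and 12 fell by limma, the same adjusted over the list alone (0 and 13 at an unadjusted p under 0.05), with ASNS, SESN2 and XBP1 lower by more than 2 on the log2 scale. That list's median of -0.89 turned to 0.49 with TMM (9 risen and 3 fallen), and PDIA4, a member that fell by 1.31, was at 0.09 with TMM. Of 14 p53 targets 2 rose and 9 fell, likewise over the list alone, with a median of -1.80 (5 and 7 with TMM, median -0.41), and ZMAT3 (-3.68), TIGAR (-3.41) and PHLDA3 (-3.37) fell.

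Most genes of the machinery that ends transcripts fell. Of 24 cleavage, polyadenylation and termination factors 0 rose and 23 fell by limma, the same adjusted over the list alone and at an unadjusted p under 0.05 (0 and 23), and their median of -2.28 lay 0.86 below that of all genes (4 rose and 19 fell with TMM). Set against genes of like siC level (10 bins), a comparison added after seeing the data, the median difference was smaller, at -0.54, and 16 of the 24 lay below the median of their bin. Besides FIP1L1, CPSF2 (-3.35) fell with SCAF4 (-3.08) and SCAF8 (-2.80), which suppress early polyadenylation. Camera placed this list below other genes (adjusted p = 0.048), but not without siC library 1 (0.065), KCl library 1 (0.078) or KCl library 2 (0.110), and at adjusted p = 0.999 with an estimated correlation. Of 28 genes for RNA polymerase II and its elongation factors 25 fell and 0 rose by limma, likewise over the list alone and at an unadjusted p under 0.05 (25 and 0), and the median was -1.70. With TMM 6 of them rose and 12 fell (median -0.31), and against genes of like siC level the median difference was 0.07 (11 of 28 below their bin). CCNT2 (-3.60) and CCNT1 (-3.04), the cyclins of the pause-release kinase, fell, as did CDC73 of the PAF1 complex (-2.45). Of 18 Integrator subunits 1 rose and 15 fell (2 and 15 adjusted over the list alone), and the median of -1.31 was at 0.09 with TMM (5 and 4). Against genes of like siC level the median difference was 0.70, with 5 of the 15 subunits placed below their bin. INTS12 (-3.64) and INTS10 (-3.63) fell, whereas INTS2 rose from 3791.5 ± 344 to 6623 ± 140. INTS7 fell by 1.67, a call lost with TMM (log2 change -0.28) and median-ratio scaling, as was that of CPSF3L (-1.75, and -0.36 with TMM).

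Replication-dependent histone genes fell less than most genes on the deposited scale, as some other lists did. Their median log2 change of 0.01 lay 1.43 above that of all genes and was 1.41 with TMM, and camera placed them above other genes (adjusted p = 1.8e-04, adjusted p = 0.999 with an estimated correlation). Set against genes of like siC level, the histone median lay 1.22 higher, with 11 of 54 below their bin. Ribosomal protein genes also lay 1.22 higher (5 of 75 below) and immediate early genes 1.02 (3 of 32 below). Of 54 histone genes 9 rose and 13 fell (8 and 10 adjusted over the list alone), and 40 rose and 0 fell with TMM. Without KCl library 1 the risen were 14, and without KCl library 2 only 1. HIST1H2BF rose from 243 ± 49.5 to 589 ± 212, while the linker histones HIST1H1D (-2.01) and HIST1H1C (-0.83) fell, the first a call lost with TMM and the second at 0.57 with TMM. Of 77 cytosolic ribosomal protein genes 2 rose and 57 fell, likewise over the list alone, and the median of -0.74 turned to 0.65 with TMM, where 56 rose and 5 fell. RPL22L1 (-2.89) and RPS23 (-1.91) fell, and RPL3L, a muscle paralogue, rose from 100.5 ± 17.7 to 861 ± 216. Of 14 spliceosomal snRNA listings 1 rose and 5 fell (1 and 4 adjusted over the list alone), and the median of -0.39 turned to 1.00 with TMM (9 and 2). RNU5D-1 (-3.83) and RNU5F-1 (-2.45) fell. RNU12 fell by 0.99, but was at 0.40 with TMM, and the rise of RNU6-1, at 0.90, was lost without KCl library 2 (0.43).

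Most growth and metabolic genes were lower on the deposited scale. Set against genes of like siC level, cell cycle genes lay at a median of 0.03 (13 of 28 below their bin). Cholesterol synthesis genes lay at 0.60 (7 of 22 below) and glycolysis and HIF1 genes at 0.46 (7 of 20 below). Of 28 S and G2/M genes 27 fell and 0 rose by limma, likewise over the list alone and at an unadjusted p under 0.05 (27 and 0), with the kinetochore genes CENPE at a log2 change of -3.09 and BUB1 at -3.25, and their median was -1.82. With TMM 6 of these rose and 13 fell (median -0.42). Of 22 cholesterol synthesis genes 20 fell and 0 rose by limma (21 and 0 adjusted over the list alone, 21 and 0 at an unadjusted p under 0.05), with MVK at -2.87, and the median of -1.27 was at 0.13 with TMM (8 risen and 8 fallen). Of 20 glycolysis and HIF1 genes 18 fell and 1 rose, likewise over the list alone. PDK1 (-3.55) and HK1 (-3.18) fell, CA9, a carbonic anhydrase, rose by 1.39, and the list's median of -1.38 was at 0.01 with TMM (7 risen and 6 fallen). Of 7 tested markers of other cell types 0 rose and 2 fell by limma (1 adjusted over the list alone, 0 and 2 at an unadjusted p under 0.05), among them COL1A1 (-1.17), with a median of -0.43 that turned to 0.93 with TMM (2 risen and 1 fallen), as COL1A1 turned to 0.20. Among the host genes known for DoGs, CXXC4 fell from 596 ± 141 to 28 ± 5.66 and OSGIN2 from 2839 ± 269 to 516 ± 46.7, 2 of 3 also when adjusted over the list alone. RSRP1 had 3164 ± 208 in siC and 2995 ± 1041 in KCl (adjusted p = 0.599), a log2 change of -0.12 that turned to 1.27 with TMM. No mitochondrially encoded gene was among those tested. Of the 77 named genes called, 68 kept their call with TMM, 5 lost it and 4 reversed.

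**Figure D1:**
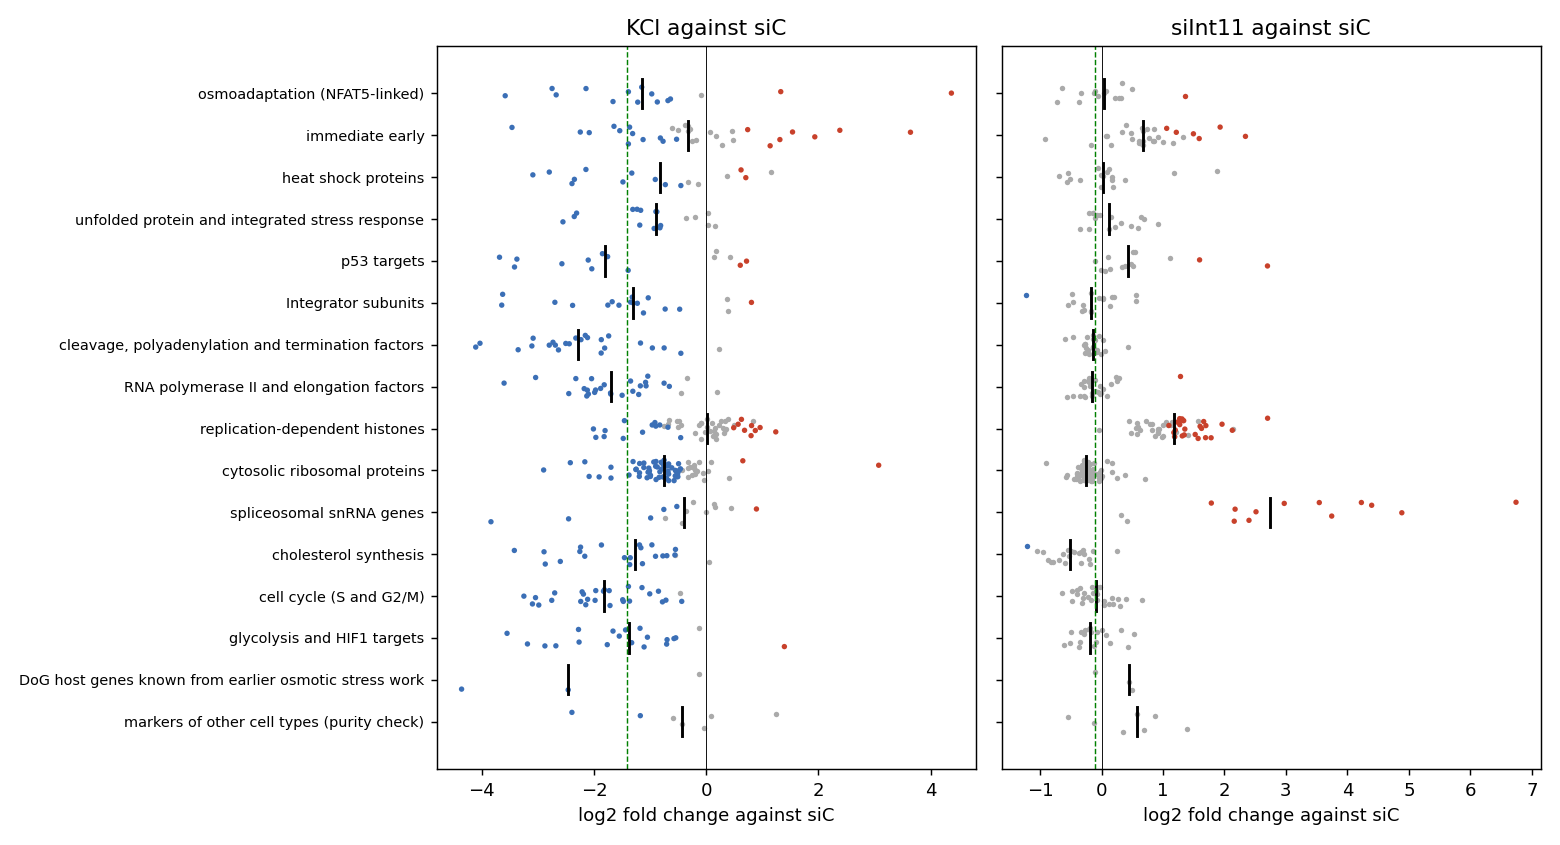
Log2 fold change against siC (x axis) of each tested member of the fixed gene lists (y axis), for KCl on the left and siInt11 on the right. Each dot is a gene, coloured where it passed the threshold (red higher, blue lower), black bars mark list medians, and the green dashed line marks the median of all genes, at -1.41 for KCl and -0.10 for siInt11. Histones sat at a median of 0.01 in KCl and 1.18 with siInt11, and the KCl medians of 10 lists below 0 turned positive with TMM scaling.

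Readthrough regions changed in both directions under KCl. DoGs of KLHL40, ADGRF4 and the adrenergic receptor ADRA2A were listed at 0 in both siC libraries and at 548.5 ± 230, 558.5 ± 457 and 406 ± 259 in KCl. Those of NPC1L1, NCCRP1, LOC101928710, ALPP and EPM2AIP1, also listed at 0 in siC, lay between 232 ± 21.2 and 283 ± 140 in KCl. By contrast the region behind the interferon gamma receptor gene IFNGR1 fell from 285 ± 42.4 to 0.5 ± 0.707, that of PPAPDC2 from 460 ± 115 to 1.5 ± 0.707, that of MBIP from 585 ± 77.8 to 3 ± 0 and that of AIMP1, a scaffold of tRNA synthetases, from 706.5 ± 175 to 4 ± 0. Of 7214 regions 2020 rose and 3969 fell, with a median log2 change of -0.91. Scaling by gene-table totals gave 3179 risen and 2408 fallen, and TMM over the regions 2796 and 3153. The region of OSGIN2, a gene known for DoG induction, fell from 641.5 ± 94 to 20 ± 4.24 (log2 change -4.94, SE 0.38, adjusted p = 4.9e-37). That of RSRP1 rose from 618 ± 63.6 to 949.5 ± 99.7 (log2 change 0.62, adjusted p = 0.033), a call lost without siC library G (0.51), KCl library G (0.73) or KCl library I (0.51). CXXC4 had no region among those used. The table holds regions that the authors picked in a way not stated, so the numbers of raised and lowered regions depend on that choice.

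Relative to their host gene, regions gained. RDX, which encodes radixin, fell as a gene from 10953 ± 1424 to 2238.5 ± 57.3, while its DoG went from 99.5 ± 27.6 to 2428.5 ± 861, a rise of the ratio by 6.86 on the log2 scale (SE 0.34, adjusted p = 1.4e-38). ISG20, an interferon-induced exonuclease gene, fell from 2485.5 ± 189 to 557.5 ± 91.2, and its DoG went from 189.5 ± 72.8 to 4797 ± 1006, with a rise of the ratio by 6.86. The ratio of 2 uncharacterised loci, LOC339539 and LOC101929162, rose by 6.79 and 6.68. It fell for LOC101928936 (-5.48), DNAJC19 (-4.90), FAM127B (-4.62), PPAPDC2 (-4.58) and OSGIN2 (-2.48). Over 7050 regions with a host row the ratio rose for 3656 and fell for 960, with a median log2 change of 0.95, a fold of 1.94. With each library as its own block, an alternative added after seeing the data, it rose for 3817 and fell for 1074. With the replicate number as a block it rose for 3617 and fell for 973, and 9 of the 10 named ratios called kept their call. Without siC library I of the region table the ratio fell for 621. The rise for RSRP1 (0.74, adjusted p = 0.046) was lost without siC library 1 (0.81), siC library 2 (0.67) or KCl library 1 (0.38) of the gene table, and without siC library G (0.64) or KCl library I (0.63) of the region table.

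Hosts of raised DoGs were mostly lower themselves, but less often than other hosts. Of 1973 raised regions with a tested host, 1277 hosts fell (64.7%), 372 rose and 324 did neither. Among 5077 other regions 93.5% of hosts fell and 30 rose, and Fisher's exact test, two-sided, gave an odds ratio of 0.127 (p = 2.6e-186, over genes, which are not replicates). The median host change was -1.01 for raised and -2.11 for other regions. With total values as scaling, 38.5% of the hosts of raised regions fell. The direction turned for regions raised relative to their host, whose hosts fell more often than others (87.2%), since the host is the denominator of that ratio.

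**Figure D2:**
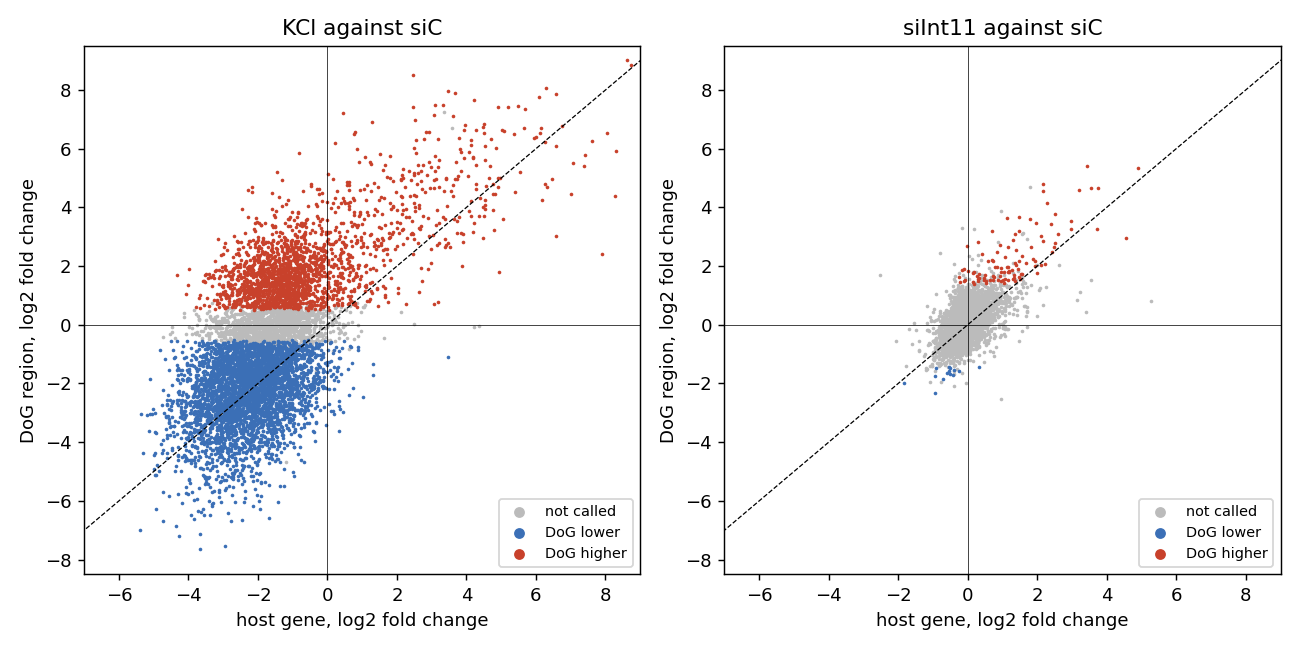
Log2 fold change of each DoG region (y axis) against that of its host gene (x axis), for KCl on the left and siInt11 on the right. Each dot is a region, red where the region passed the threshold upward and blue downward, and the dashed line marks equal change. In KCl the dots lie above the line at a median of 0.95, and of the hosts of raised regions 64.7% fell, or 38.5% with total values as scaling.

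Loss of Int11 raised spliceosomal snRNA genes transcribed by RNA polymerase II, and the regions behind them. RNU1-1, the U1 snRNA of 5' splice site recognition, rose from 1328.5 ± 353 to 24553.5 ± 2972 (log2 change 4.23, SE 0.32, adjusted p = 2.3e-37). RNU4-1 rose from 155 ± 1.41 to 3285.5 ± 238, RNU4ATAC of the minor spliceosome from 270.5 ± 112 to 3496 ± 481, and RNU5B-1 from 65 ± 62.2 to 1457 ± 148. RNU2-1 went from 2886 ± 2664 to 234723 ± 18352 (log2 change 6.74, SE 0.37, adjusted p = 2.4e-21). Of 14 snRNA listings 12 rose and 0 fell, the same adjusted over the list alone. Both that did not pass were listings of RNU6-1, the U6 gene of RNA polymerase III, one at 1156.5 ± 278 and 1449.5 ± 409 (log2 change 0.32). The list had a median of 2.74 and camera placed it above other genes (adjusted p = 5.8e-58, adjusted p = 0.181 with an estimated correlation). Without siC library 1 it had 9 risen members, and without siC library 2 it had 6. The RNU2-1 call was lost with TMM, median-ratio and total-value scaling at log2 changes of 6.84 to 6.88, and without siInt11 library 1 (6.82) or 2 (6.66). It was also lost with the replicate number as a block (6.74). The change kept its size each time, and the siC values of RNU2-1 lay far apart, at 1002 and 4770. The RNU5B-1 call was lost with the same scalings.

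Over all genes 353 of 18995 rose and 102 fell with siInt11, and the median gene changed by -0.10. Human TMM scaling gave 2510 and 2352, median-ratio scaling 2522 and 2331, and total values 2879 and 1915. The numbers moved widely when a library was left out. A fit without 1 siC library takes its spread from the siInt11 pair alone, which differed by a median of 0.46 on the log2 scale. A fit without 1 siInt11 library takes it from the siC pair, which differed by 0.24. These counts thus depend on the offset of the pair that remains, and not only on the library left out. With 2 prior degrees of freedom, an alternative added after seeing the data, limma called 0 genes, with 1029 at an unadjusted p under 0.05, against 2025 in the fit reported here. Of the 32 named genes called, 12 kept their call without siC library 1, and 12 without siC library 2.

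The 5 called genes that rose more than RNU2-1 were loci with low siC values. MIR3675 rose from 12.5 ± 2.12 to 5755 ± 2178 (log2 change 8.69, SE 0.45, adjusted p = 2.2e-77), FAM231B from 31 ± 28.3 to 7385.5 ± 839, MST1P2 from 36.5 ± 17.7 to 5571.5 ± 1522 and MST1L from 35 ± 14.1 to 5483 ± 2524. FAM231A went from 2 ± 2.83 to 1611.5 ± 506 and SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, from 3 ± 4.24 to 119.5 ± 57.3. MIR3675, MST1P2 and MST1L lie within 50 kb of a snRNA gene in the GRCh38 annotation. The largest falls were those of SIGLEC10, a sialic acid receptor (619.5 ± 163 to 23.5 ± 10.6, log2 change -4.71, adjusted p = 3.9e-15), and GALNT14, a glycosyltransferase (1027.5 ± 70 to 108 ± 49.5, log2 change -3.31). CECR1, IFI44L, CHRND, SBSN, WWC3 and TEDDM1 fell, at log2 changes of -2.57 to -2.26, and each of these 6 lost its call without siC library 1 and without siC library 2, at -2.83 to -2.06. IFI44L also lost it without siInt11 library 2 (-1.83), WWC3 without siInt11 library 1 (-1.56), and SBSN without siInt11 library 1 (-0.50) and with each of the 3 scalings.

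Histone genes, and some immediate early and p53 target genes, rose with siInt11. Of 54 replication-dependent histone genes 25 rose and 0 fell (40 and 0 adjusted over the list alone, 36 and 0 over all genes with TMM, 38 and 0 with total values), with HIST1H3B at 6251 ± 816 in siC and 21190 ± 9081 in siInt11, and HIST1H3A, HIST1H4C and HIST1H2AM higher by 1.96, 1.78 and 1.63 on the log2 scale. Their median was 1.18, 1.29 above all genes, and camera gave an adjusted p of 6.5e-26 (adjusted p = 0.948 with an estimated correlation). HIST1H2AM lost its call with each scaling, at 1.73 to 1.76, and with the replicate number as a block (1.63). The risen histones were 0 without siC library 1, 0 without siC library 2, 41 without siInt11 library 1 and 7 without siInt11 library 2. Of 32 immediate early genes 6 rose and 0 fell (9 and 0 adjusted over the list alone, 18 and 0 over all genes with TMM, 21 and 0 with total values), among them FOS from 671.5 ± 172 to 2637 ± 1104, BTG2 from 954.5 ± 142 to 2834.5 ± 1316, ARC (2.34) and GADD45B (1.59), with a median of 0.68 and a camera adjusted p of 8.4e-08 (adjusted p = 0.948 with an estimated correlation). Without siC library 1 or siC library 2 none passed (0 each), without siInt11 library 1 there were 21 and without siInt11 library 2 there were 3, with GADD45B lost (0.86). Of 14 p53 targets 2 rose and 0 fell (3 and 0 adjusted over the list alone, 9 and 0 over all genes with TMM and with total values), CDKN1A, the p21 cell cycle inhibitor, from 727.5 ± 43.1 to 2280 ± 856 and GDF15 from 26 ± 1.41 to 191.5 ± 112. The list's median was 0.43 (camera adjusted p = 0.0051, adjusted p = 0.948 with an estimated correlation), with 0 risen without either siC library, 3 without siInt11 library 1 and 1 without siInt11 library 2, with GDF15 lost (2.07).

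Of 22 cholesterol synthesis genes 1 fell and 0 rose by limma (3 and 0 adjusted over the list alone, 8 and 0 at an unadjusted p under 0.05). With TMM 12 fell and 1 rose, and with total values 12 and 1. The list's median was -0.51 (camera adjusted p = 0.0022, adjusted p = 0.948 with an estimated correlation), and the fallen were 0 without either siC library and 9 without siInt11 library 2. Of 15 osmoadaptation genes SGK1 alone passed, at a log2 change of 1.35, of 18 Integrator subunits CPSF3L alone, and of 28 polymerase II and elongation genes HEXIM1 alone (1.27), an inhibitor of the pause-release kinase, whose call was lost with TMM (1.37) and without siInt11 library 2 (0.57). Adjusted over the list alone these counts were 1 risen, 1 fallen and 1 risen, and SGK1 and HEXIM1 lost their calls without siC library 1 (1.21 and 1.19) and without siC library 2 (adjusted p = 0.883 and 0.898), as SGK1 did without siInt11 library 2 (0.79). By limma 0 members passed of 17 heat shock genes, 17 genes of the unfolded protein and integrated stress response, 24 cleavage and termination factors, 77 ribosomal protein genes, 28 cell cycle genes, 20 glycolysis genes, 3 known DoG hosts and 7 markers of other cell types, and again 0 adjusted over the list alone. At an unadjusted p under 0.05 these counts were 2 (1 up, 1 down) for heat shock genes, 2 for the stress response, 1 for ribosomal protein genes, 1 for cell cycle genes and 0 for each of the others. With TMM the risen and fallen were 1 and 2 for heat shock, 5 and 0 for the stress response (7 and 0 with total values), 1 and 2 for cleavage and termination, 3 and 11 for ribosomal proteins, 5 and 3 for the cell cycle, 2 and 4 for glycolysis, 2 and 0 for DoG hosts and 0 and 1 for other cell types. With TMM they were 3 and 4 for osmoadaptation, 4 and 2 for Integrator and 2 and 3 for polymerase II and elongation. OSGIN2 had 2839 ± 269 in siC and 2669.5 ± 640 in siInt11, and RSRP1 3164 ± 208 and 4740 ± 2205.

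In the DoG table, snRNA regions led with siInt11. The region behind the second RNU1-1 listing rose from 558 ± 5.66 to 37058 ± 1826 (log2 change 6.05, SE 0.41, adjusted p = 4.1e-45), and the other 7 RNU1-1 listings rose by 3.82 to 5.98. The RNU2-1 regions rose from 1551 ± 25.5 to 86731 ± 11567 and from 5553 ± 436 to 206364 ± 32113, the region of RNVU1-7, a variant U1 gene, from 388 ± 70.7 to 16314 ± 2693, and that of RNU5B-1 from 402 ± 35.4 to 16247 ± 771. Of 21 snRNA regions 19 rose. The largest falls were in the regions of ATF5, a stress transcription factor gene (348.5 ± 43.1 to 78.5 ± 54.4), TMEM143, CECR5-AS1 and GPR157, at log2 changes of -2.32, -1.98, -1.85 and -1.75, and each lost its call without siC library G (-2.45, -2.31, -2.09 and -1.77) and without siC library I (-2.20, -1.65, -1.61 and -1.73). OSGIN2 (641.5 ± 94 to 463 ± 127) and RSRP1 (618 ± 63.6 to 833.5 ± 380) did not pass. In all 119 of 7115 regions rose and 14 fell, with a median log2 change of 0.05. With TMM 1133 rose and 1064 fell, without siC library G 23 and 0, without siC library I 34 and 0, without siInt11 library G 521 and 30, and 139 fell without siInt11 library I. With 2 prior degrees of freedom limma called 0 regions, with 330 at an unadjusted p under 0.05, against 665 in the fit reported here.

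Relative to the host gene, the number of regions called with siInt11 depended on the model. In the fit reported here, which recovered 0% of simulated 2-fold and 55.2% of simulated 4-fold ratio changes, the ratio rose for 11 of 6937 regions and fell for 1 (292 at an unadjusted p under 0.05). With each library as its own block, an alternative added after seeing the data, it rose for 1016 and fell for 150 (2102 at an unadjusted p under 0.05). Those of largest rise were the pseudogene SUGT1P3 (3.44), LINC00910 (2.70, DoG 618 ± 154 to 3928 ± 137), RNU12 (2.63) and C21orf91 (2.55). The ratio of ARF6 fell by 4.45, a call lost without siInt11 library G (-4.62) or I (-4.27) of the region table and with each library as its own block (adjusted p = 0.188). By library left out, the risen were 4 without siC library 1 of the gene table, 0 without siC library 2, 3 without siInt11 library 1, 4 without siC library G of the region table and 57 without siInt11 library G, and the fallen were 3 without siInt11 library I and 0 without siInt11 library G. Of 103 raised regions with a tested host, 46 hosts rose, 57 did neither and 0 fell. Of 6834 others 38 rose and 10 fell (0.146%), too few for a test on fallen hosts to tell.

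Many regions stood at different levels in KCl and siInt11 by a direct test that needs no siC library. The regions of RNVU1-7 and RNU5D-1 were at 16314 ± 2693 and 33715.5 ± 101 in siInt11 and at 34 ± 11.3 and 126 ± 48.1 in KCl (log2 changes -8.89 and -8.11, SE 0.44 and 0.43). MBIP and PPAPDC2 were at 854 ± 264 and 465.5 ± 57.3 in siInt11 and at 3 ± 0 and 1.5 ± 0.707 in KCl. Higher in KCl were the regions of the olfactory receptor gene OR2K2 (10.5 ± 2.12 in siInt11, 1671.5 ± 378 in KCl), TRIM72, a membrane repair gene (35 ± 35.4 and 3052.5 ± 832), SDC1, the syndecan-1 gene (23 ± 15.6 and 2169 ± 501), KLHL40 (2.5 ± 0.707 and 548.5 ± 230), ADGRF4 (3.5 ± 0.707 and 558.5 ± 457) and C1orf64 (3 ± 4.24 and 403.5 ± 115). FAM19A3 and TEX33 were listed at 0 in siInt11 and at 197 ± 137 and 96 ± 22.6 in KCl. The region of OSGIN2 was lower in KCl (463 ± 127 and 20 ± 4.24), and that of RSRP1 had an adjusted p of 0.593. Of 7214 regions 1576 were higher in KCl and 3623 lower. TMM gave 2833 and 3098, gene-table totals 2641 and 2260, and 825 were higher without KCl library G, and 632 higher and 2316 lower without KCl library I.

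Of the 119 regions raised by siInt11, 57 were also raised by KCl, among 1921 raised by KCl of the 7115 tested in both. Independent lists would share 32.1. Unchanged groups simulated against the same siC libraries shared 2.37 on average and 8 at most. Groups without change hold few raised regions, so that number is no baseline for lists of 119 and 1921. Part or all of the excess over 32.1 may come from the shared controls, which are too few to split. Another 36 of the 119 fell in KCl, where independent lists would give 66.4. Of the 14 regions lowered by siInt11, 12 were lowered by KCl, where 55.0% of all regions fell. Both comparisons share the siC libraries. Over all regions the covariance of both log2 changes was 0.305 and the simulated covariance 0.0339, a difference of 0.271. Their correlation was 0.225 and the simulated one 0.459. The simulated changes hold noise alone, so these 2 correlations cannot be compared. The shared number was 2 without siC library G, 12 without siC library I, 221 without siInt11 library G and 32 without siInt11 library I, and 558 with TMM. With the replicate number as a block the shared number was 283. The number for independent lists was worked out for the reported fit alone, so no excess is shown for these alternatives. The regions of snRNA genes were not among the shared ones for the most part, since 2 of 21 rose and 12 fell in KCl.

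The rescues asked whether the catalytic site of Int11 is needed to restore these levels, and with 1 library each they are described without a test. At snRNA genes wild-type Int11 brought values back toward siC and E203Q did not. RNU2-1 had gene values of 1002 and 4770 in siC and 221746 and 247700 in siInt11, and stood at 9925 with wild-type Int11 and 334861 with E203Q. RNU1-1 stood at 1578 and 1079 in siC, 22452 and 26655 in siInt11, 2689 with wild type and 30641 with E203Q. The region behind RNU12 had 663 and 813 in siC, 19675 and 21262 in siInt11, 1464 with wild type and 28693 with E203Q. Over the 21 snRNA regions the median log2 ratio to the siC mean was 4.55 and 4.77 in the siInt11 libraries, 0.98 with wild type and 4.97 with E203Q, and E203Q was above wild type in 21 of 21 with a median difference of 3.82. For the 14 snRNA genes these medians were 2.63, 2.86, 1.04 and 2.90, and E203Q was above wild type in 13 of 14.

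Other risen genes and raised regions stood, by their medians, between siC and siInt11 with wild-type Int11, while fallen genes had not returned. For 341 other risen genes the medians were 1.5 and 2.20 in siInt11, 1.08 with wild type and 2.12 with E203Q, and E203Q was above wild type in 330, by a median of 0.95 where all genes differed by 0.29. For 100 other raised regions they were 1.62, 2.24, 1.37 and 2.15, and E203Q was above wild type in 97, by a median of 0.62 where all regions differed by 0.18. For the 102 fallen genes the medians were -1.56 and -1.13 in siInt11, -1.47 with wild type and -1.33 with E203Q. E203Q was above wild type in 65 of them, by a median of 0.13, less than the 0.29 by which all genes differed. These sets were chosen against the same siC libraries that the ratios use, which favours large medians. Library medians over all genes, relative to the siC mean, were -0.33 and 0.14 for siInt11, -0.39 for wild type and -0.07 for E203Q. Single genes differed: HHAT, the Hedgehog acyltransferase gene, chosen after its values were seen, stood at 3174 and 3669 in siC, 34408 and 39908 in siInt11, 4115 with wild type and 41830 with E203Q, and FRZB, a Wnt antagonist gene chosen in the same way, at 32 and 56, 404 and 790, 395 and 489.

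**Figure D3:**
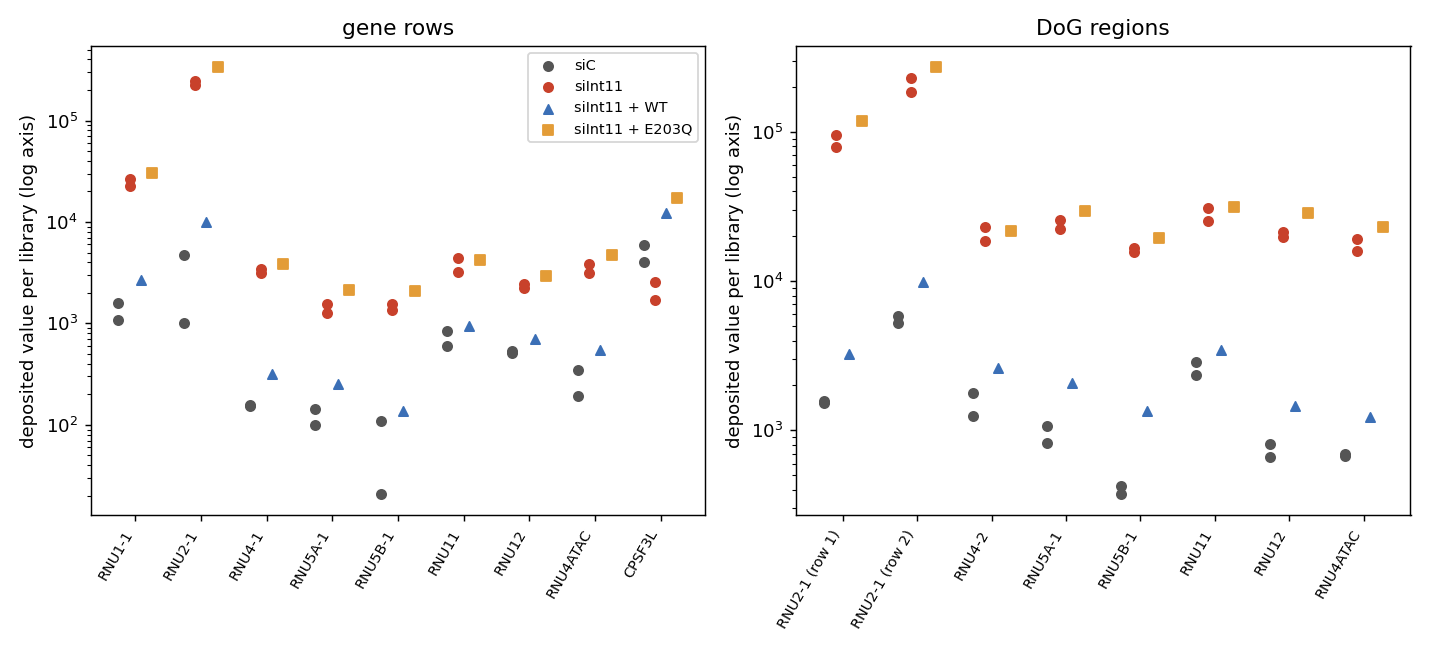
Deposited values per library on a log axis (y axis) for snRNA genes and CPSF3L on the left and for DoG regions of snRNA genes on the right (x axis), with a point per library of siC, siInt11 and each rescue. RNU2-1 stood at 9925 with wild-type Int11 and at 334861 with E203Q, against 1002 and 4770 in siC.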

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

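The pseudocount of 10, limma without the robust option, 2 prior degrees of freedom, the ratio tables put on 1 scale, the ratios with each library as its own block and the fit of the rescues are tests chosen after seeing the data. Of 255 summary values under an alternative, 183 stayed within 1.5 times the reported count or on the same side of the threshold. Of 2752 values of named genes and regions 2410 kept direction and side of the threshold, 157 gained a call, 160 lost it and 25 changed sign. Of 192 values of gene lists 180 kept both, 7 gained a call and 5 lost it. With 2 libraries per group and a spread pooled over genes, many siInt11 calls depend on which libraries give the spread. A library left alone in its group was assumed to vary like the others. Values of a few reads limit the folds of genes that are silent in a group. The count tools, voom and spike-in scaling were not run, because the values are scaled and hold no Drosophila genes. Where a value below changed and no reason is given, the cause was not tested.

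Scaling moved the general level of KCl. TMM gave 6516 risen and 6896 fallen genes, median-ratio scaling 6626 and 6814, and total values 5529 and 8127, since each of these centres the libraries by construction. The sign changed with TMM for PDIA4 (0.0885), HIST1H1C (0.57), RNU12 (0.40), RSRP1 (1.27), COL1A1 (0.20) and COL3A1 (0.77), with median-ratio scaling for the same 6 (0.11, 0.59, 0.42, 1.29, 0.22 and 0.79), and with total values for HIST1H1C (0.35), RNU12 (0.18), RSRP1 (1.05) and COL3A1 (0.55). Of the 77 named genes called for KCl, 68 kept their call with TMM, 68 with median-ratio scaling and 72 with total values. For siInt11 TMM gave 2510 risen and 2352 fallen genes, median-ratio scaling 2522 and 2331, and total values 2879 and 1915, and 27 of 32 named calls were kept with each. OSGIN2 turned to 0.0284 with total values. For DoG regions in KCl, gene-table totals gave 3179 risen and 2408 fallen, and for siInt11 TMM gave 1133 and 1064. Between KCl and siInt11 2833 regions were higher in KCl with TMM, and 2641 higher and 2260 lower with gene-table totals. All 14 named regions called for KCl, all 12 for siInt11 and all 13 between both kept their call with TMM. The overlap of raised regions was 558 with TMM. Of the hosts of regions raised by siInt11, 0% fell with total values, now past the threshold of Fisher's test. The median of fallen genes in the wild-type rescue was -1.10 with TMM and -1.07 with total values, against -1.47 as deposited. In the E203Q rescue it was -1.23 and -1.09, against -1.33. The median of all 353 risen genes moved away from siC, to 1.45 and 1.48 with wild type, against 1.08 as deposited. With E203Q it was 2.24 and 2.37, against 2.14. Ratio tables put on 1 scale, a shift of 0.09 log2, gave 3789 risen and 888 fallen.

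The fit mattered most for siInt11. With the replicate number as a block, 1605 genes rose and 1950 fell, 680 regions rose and 319 fell, the ratio rose for 248 and fell for 31, the overlap was 283, and 1.08% of the hosts of raised regions fell, now past the threshold. Of 32 named genes 30 kept their call and RNU2-1 (6.74, adjusted p = 0.240) and HIST1H2AM (1.63, adjusted p = 0.431) lost it, while 22 immediate early, 47 histone and 6 p53 genes rose and 12 cholesterol genes fell. Residuals of like-numbered libraries correlated at 0.02 and 0.12 for genes and -0.02, -0.02 and 0.07 for regions, which gives little ground for pairing gene by gene. This correlation cannot see a shift common to all genes, which the block also takes out. Library 2 lay above library 1 by a median of 0.24 in siC, 0.21 in KCl and 0.46 in siInt11. For regions library I lay above G by 0.27, 0.02 and 0.57. The fit reported here counts that shift as spread. The block changed KCl less (2442 risen and 13692 fallen genes), though camera no longer called the cleavage, polyadenylation and termination factors (adjusted p = 0.064). With each library as its own block, tied between tables by the step of low values, the siInt11 ratio rose for 1016 and fell for 150 regions and lost ARF6 (-4.45, adjusted p = 0.188), and the KCl ratio rose for 3817 and fell for 1074. The block takes out what gene and region share within a library, which the reported fit counts as spread. With all libraries of the table in the fit, 221 regions rose and 45 fell with siInt11. With 2 prior degrees of freedom the t-test outside limma called 0 genes risen and 0 fallen for siInt11 (1029 at an unadjusted p under 0.05). For regions it called 0 and 0 (330), while KCl kept 1794 risen and 12037 fallen genes and 1754 and 3628 regions. So few degrees of freedom leave little room for calls unless many genes change. Without the robust option siInt11 gave 423 and 121 genes, and 120 and 15 regions. With an estimated correlation camera called 0 lists for KCl, where 3 were called with the preset one, and 0 for siInt11, where 5 were. With a 2-fold minimum 2007 genes rose and 11619 fell in KCl. Of the hosts of regions raised relative to their host in KCl, 87.2% fell, more often than other hosts and so a reversed direction, because the host is the denominator of that ratio. A limma fit of each lone rescue library had to assume that it varied like the others, so its counts are not given and no test of the rescues rests on it.

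Leaving out each library in turn gave 1408 to 2335 risen and 11534 to 13387 fallen genes for KCl, and 50 to 806 and 2 to 710 for siInt11. Regions in KCl came to 1620 to 2022 risen and 3330 to 3805 fallen, with siInt11 to 23 to 521 and 0 to 139, and between both to 632 to 2052 higher and 2316 to 3908 lower in KCl. The ratio rose for 3247 to 3793 and fell for 621 to 1017 regions in KCl, the low end without siC library I of the region table. With siInt11 it rose for 0 to 57 and fell for 0 to 3. It rose for 4 without siC library 1 of the gene table, 0 without siC library 2, 3 without siInt11 library 1, 4 without siC library G of the region table and 57 without siInt11 library G, and fell for 0 without siInt11 library G and 3 without siInt11 library I. Fallen hosts of raised regions were 60.5 to 67.7% for KCl and 0 to 0% for siInt11. The overlap was 2 to 221 regions, and the lists called by camera 2 to 3 for KCl and 5 to 7 for siInt11. Without siC library 1, 12 of 32 named siInt11 genes kept their call, and 12 of 32 without siC library 2. For named siInt11 regions, 8 of 12 calls were kept without siC library G, and 8 of 12 without siC library I. Values not past the threshold changed sign for RSRP1 as a gene in KCl (-0.48 to 0.24, the high end without KCl library 1), and with siInt11 for OSGIN2 (-0.35 to 0.14, the high end without siInt11 library 1), PECAM1 (-0.0805 without siC library 1 to 1.82) and RPS29 (-1.32 to 0.18, the high end without siC library 2). The RSRP1 region ranged from -0.13 without siInt11 library I to 0.84 with siInt11, and from -0.22 without siInt11 library G to 0.74 between KCl and siInt11, and its ratio turned for siInt11 to 0.35 without siInt11 library 2 and 0.34 without siInt11 library G.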

Other observations

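The genes in the next 2 paragraphs were chosen after their values were seen, and so were 2 of the tests on the general KCl drop and the control for neighbouring genes. Regions behind some snoRNA genes, and behind RPPH1, which is not a snoRNA gene, rose with siInt11. They were not tested as a group. Of the U3 genes, SNORD3D went from 2621.5 ± 599 in siC to 9946 ± 1928 in siInt11 (log2 change 1.93, adjusted p = 3.5e-04), SNORD3B-1 from 2057 ± 352 to 7213 ± 379 (1.82) and SNORD3A from 2997 ± 129 to 9529 ± 1496 (1.66). The region of SNORD3C, from 1678 ± 29.7 to 4319.5 ± 511, had an adjusted p of 0.0556 (2.1e-07 with TMM). SNORD118, the U8 gene, rose from 446 ± 79.2 to 1318 ± 55.2 (1.57, adjusted p = 0.0146), SNORD13 from 152.5 ± 47.4 to 499 ± 52.3 (1.73), and RPPH1, the RNA of RNase P, from 242.5 ± 79.9 to 1095.5 ± 288 (2.19, adjusted p = 6.0e-05). In the rescues, each a single library, the regions of SNORD3D, SNORD118 and SNORD13 stood at 2477, 504 and 135 with wild-type Int11 and at 10693, 2474 and 875 with E203Q, while RPPH1 stood at 639 and 1338. Each of these calls was lost without siC library G (adjusted p = 1 for each) and without siC library I (adjusted p of 0.196 for RPPH1, 0.544 for SNORD3D and 0.939 to 1 for the others), and kept without either siInt11 library. In KCl the U3 regions rose as well, by 1.14 for SNORD3A, 1.39 for SNORD3B-1, 1.24 for SNORD3C and 1.34 for SNORD3D, past the threshold without each library in turn and with TMM. The region of SNORD118 did not pass in KCl (0.39, adjusted p = 0.201), and the SNORD118 gene fell by 0.69 but was at 0.71 with TMM. With siInt11 the genes SNORD118 (1.32, adjusted p = 0.0059) and SNORD3B-1 (1.18, adjusted p = 0.0143) rose by limma. The genes SNORD3A, SNORD3C, SNORD3D, SNORD13 and RPPH1 did not pass with siInt11 (adjusted p = 0.0714 to 0.481).

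Besides SPRY4, 3 of 7 further genes tied to feedback of the ERK pathway rose with siInt11, which was not tested as a group. ETV5, an ETS factor gene, rose from 58 ± 2.83 to 711 ± 225 (log2 change 3.56, adjusted p = 1.2e-10), and stayed past the threshold without each library in turn. SPRED2, an inhibitor of RAS signalling, rose from 2979 ± 5.66 to 10574.5 ± 3105 (1.80, adjusted p = 4.5e-06), but had adjusted p values of 0.438 without siC library 1 and 0.25 without siC library 2. DUSP6, the ERK phosphatase gene, rose from 8 ± 0 to 100.5 ± 36.1 (adjusted p = 0.002), with 0.0795 without siC library 1. SPRY2 (0.92), SPRED1 (0.85), DUSP4 (1.39) and ETV4 (0.70) did not pass, but did with TMM (adjusted p = 2.0e-05, 1.4e-04, 0.0027 and 0.00646). With wild-type Int11 and E203Q the single libraries stood at 233 and 1637 for ETV5, 7202 and 13573 for SPRED2, and 61 and 193 for DUSP6. In KCl SPRED1 (-3.79) and SPRY2 (-3.35) fell, as did DUSP4 (-2.11) and SPRED2 (-1.66), which were at -0.75 and -0.27 with TMM and no longer passed (adjusted p = 0.150 and 0.154). DUSP6 rose in KCl (1.83, adjusted p = 0.0336, or 3.11 with TMM), a call lost without siC library 1 (adjusted p = 0.0542).

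In the first pattern weighed, the general drop in KCl, the medians of the nearest siC and KCl libraries lay 1.16 apart on the log2 scale, which argues against scatter of the scaling between libraries of a group. With TMM 51.4% of the called genes were lower in KCl, which centring alone can give, so a wrong factor shared by both KCl libraries and a true drop of transcription, the salt being the design's biological explanation, cannot be told apart. Rows of the ribosomal RNA repeat summed to 7.6 and 10.89 M in siC and 7.69 and 8.38 M in KCl, so the composition of the libraries moved with the drop, and carry-over of unlabelled RNA was not tested. Polymerases already on long genes when the salt came may have left them less affected: genes over 200 kb changed by 0.563 log2 more upward than genes under 20 kb of like siC level (95% bootstrap interval 0.459 to 0.696). As this interval includes values under the 0.5 set beforehand, and 1 of 10 bins of siC level went the other way, the test left that open. Genes of 20 to 50, 50 to 100 and 100 to 200 kb fell more (medians -1.72, -1.82 and -1.59) than genes under 5 kb (-1.19). These medians are not matched on siC level, so they do not bear on the matched test.

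The second pattern is the rise of genes with low siC values in KCl. Genes under the filter's minimum in both siC libraries were tested only where both KCl values reached it. The lowest siC levels thus hold some genes picked for their KCl values. In the lowest of 10 bins of siC level (median 24) 52.3% rose, with a median log2 change of 1.56. In the next bin (median 83) 22.5% rose, with a median of -0.67. How much of the pattern this filter makes was not tested. Reads of a converging neighbour whose region rose may account for part of the rise. Such neighbours had a common odds ratio of 5.56 (4.58 to 6.74) in risen genes. For neighbours whose region did not rise it was 1.56 (1.36 to 1.80). For same-strand neighbours upstream the odds ratio was 4.07 (3.27 to 5.06), against 3.10 (2.72 to 3.54) for those not raised, so readthrough and the density of genes cannot be told apart there. Of 1595 risen genes in bins 1 to 3 of siC level, 361 had a neighbour of either kind (22.6%, and 5.17% of the others of those bins). Most had none that was counted. Only neighbours within 50 kb that the annotation placed and whose listed region rose were counted, so other sources are missed. KLHL40 and CXorf36 face the raised regions of CCDC13 and KDM6A, and CTAGE11P lies behind TBC1D4.

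The third pattern is the rise of genes other than snRNA genes with siInt11. Readthrough from a nearby snRNA gene was tested as its source, and 3.17% of these genes (9 of 284 that the annotation placed) lay within 50 kb of one, under the tenth set beforehand, against 0.16% of the others (odds ratio 20.4, Fisher's exact test, two-sided, p = 5.2e-09). This argues against it for most, and leaves it open for those 9, MIR3675, MST1P2, MST1L, MIR5087, MIR6077, TMEM106A, ESPNP, CROCCP2 and NBPF1. Variant U1 and other snRNA listings were taken out of the risen genes after a first count, with the same outcome. Loss of Int11 remains the design's biological explanation, untested beyond the single rescue libraries.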
